A study of Homo sapiens with 9 samples.

How the data were processed

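Natural killer cells that carry CD45 and CD56 and lack CD3 were sorted from human endometrium, the lining of the uterus, and their poly(A) RNA was sequenced, per the labels' protocols. Each of the 9 libraries belongs to a natural implantation window (4 libraries, replicates 2 to 5) or to superovulation, the hormonal stimulation of the ovaries used in assisted reproduction (5 libraries, replicates 1 to 5). The labels call the libraries biological replicates. Libraries were made with the NEBNext Ultra kit after oligo(dT) selection and read as paired ends on an Illumina HiSeq, and base calls were converted with bcl2fastq 2.17, per the labels' protocols. Trimmomatic 0.36 and the GRCh38 build are named in the submitters' processing notes. The aligner, the counting tool and the annotation release are not given in the sources used here, and neither is whether counting used strand. Coordinates are those of the deposited table, on GRCh38 per the submitters' processing notes.

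The deposited table lists 60168 genes with 9 columns of abundances that the authors had normalized between libraries, a signal on the scale of read counts that the values show is not divided by gene length. The same table holds the authors' own comparison, with a log2 fold change, a p-value and an adjusted p per gene, under column names that DESeq2 writes per the file headers. A shorter deposited list of 187 genes holds the authors' linear fold ratio and p-value for each gene. The table has 0 columns of samples outside the 9 libraries. Column totals of the deposited abundances ranged from 11.93 M to 14.53 M (M, 10 to the power 6). Because the authors had already scaled the libraries, these totals do not give the depth, and the number of reads per library is not given in the sources used here. Between 62.8% and 73.2% of the low values in a library, those up to 20.5 times its commonest low value, lay within 0.1 of a whole multiple of that value. Whole reads were therefore not recovered, and no test that needs counts was run.

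The plan fixed before the data were examined named a count test for a table of counts and limma on log2(value + 1) for normalized values, so limma was used. Each gene was tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with group as the only term, a mean-variance trend and robust moderation, and Benjamini-Hochberg adjustment. Genes entered when their value was at least 10 in at least 4 libraries, a filter the plan had not set for normalized values. A total of 15762 genes passed. Fold changes are superovulation over natural, as differences of group means on the log2(value + 1) scale. This scale can understate the change of low genes, while libraries near 0 can overstate it. For example, TBC1D3L, at 0 in some natural libraries, had a log2 fold change of 3.83 here and 1.54 in the authors' comparison. Rows of the Y chromosome and the X inactivation transcript were left out. A reference symbol was found for 59877 rows by gene ID, and 126 protein-coding rows that carried a clone name took the reference symbol.

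Gene lists for the tissue and treatment, 35 in all, were fixed before the data were examined. Camera with a preset correlation of 0.01 tested the 32 lists with at least 5 tested members against all other genes. Camera with an estimated correlation and fry were run beside it. Markers of cells outside the sorting gate were also compared as the mean log2(CPM + 1) of each list per library, with a two-sided exact permutation test over the 126 assignments of 9 libraries into 4 and 5. The same test, not named in the plan for this use, was run on the mean log2(value + 1) of the tested members of each of the 35 lists. The smallest p this test can give is 0.0159. CPM here is the deposited abundance scaled so that the mean column total is 1 M.

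Genes were named by a rule fixed before the data were examined. It took the 12 largest positive and the 12 largest negative log2 fold changes among genes past an adjusted p of 0.05 with a mean CPM of at least 5 in the higher group. Where fewer passed, it was filled with the genes of smallest unadjusted p at that CPM in each direction. Up to 4 members per list with the smallest unadjusted p and the gate genes PTPRC, NCAM1, CD3D, CD3E and CD3G were added. Of the genes this rule named, 4 are not reported here. Immunoglobulin, T cell receptor, KIR and HLA genes are described only as groups, because people differ in gene content and copies share reads.

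The limma step was tested on simulated values for the same 15762 genes, drawn from their means and spreads in this comparison, with 4 sets of 50 genes changed. At an adjusted p of 0.05, limma recovered 0 of 50 genes changed 1.5-fold, 9 of 50 changed 2-fold, 32 of 50 changed 4-fold and 40 of 50 changed 8-fold, with 4 false calls. In the simulated lists, camera called the raised list and 0 of the unchanged ones. The simulated errors were independent between genes, so this does not test lists whose genes move together. All 4 sets were changed in the same fit, so the strongly changed genes eased the adjusted threshold for the rest. In the simulation 4.82% of unchanged genes had an unadjusted limma p under 0.05, against 1.95% of all genes in the real libraries. The recovered counts are therefore not the power of limma on the real values.

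Alternatives covered median-of-ratios scaling, sample quality weights, no filter on low values, a filter at a CPM of 5 in 4 libraries, the replicate number as a block, removal of immunoglobulin, T cell receptor, KIR and HLA genes from the fit, a pseudocount of 0.1, and leaving out each library in turn. Library totals, quantile normalization, the leading component of the residuals as a covariate, and a fit without natural replicates 2 and 3 were added after seeing the data. Natural replicates 2 and 3 were picked for that fit because they were the 2 natural libraries with the most epithelial marker RNA. Superovulation replicates 1 and 2 stayed in it, with mean log2 levels of tested epithelial markers of 5.47 and 6.20. Natural replicate 2 was at 5.43, so the fit does not show the comparison without epithelial RNA.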

Results

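Endometrial natural killer (NK) cells were profiled by RNA sequencing to ask how the maternal immune cells of the uterus differ between a natural implantation window and a superovulated cycle. There were 4 natural and 5 superovulation libraries. The authors' normalized abundances summed to 13.31 ± 1.01 M per natural library (SD, n = 4) and 13.13 ± 0.80 M per superovulation library (SD, n = 5). A total of 14671 to 16264 genes per library reached an abundance of 10. The read depth behind the normalized values is unknown.

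The libraries of both groups carried the transcripts of NK cells at high levels. GNLY, which encodes the cytolytic protein granulysin, ranked first of all genes, at 569000 ± 359000 in natural (SD, n = 4) and 521800 ± 284000 in superovulation (SD, n = 5). NKG7, a granule membrane protein, averaged 43290 and 39400 in natural and superovulation, and KLRC1, an inhibitory receptor that pairs with CD94, averaged 23970 and 17900. Of the genes behind the sorting gate, PTPRC (CD45) was at 17568 ± 4331 in natural and 14435 ± 3601 in superovulation, and NCAM1 (CD56) at 6089 ± 1644 and 4916 ± 1653. CD3D averaged 582.5 and 287.0, and CD3G averaged 42.1 and 5.04, below the filter for testing. CD3E was far more abundant than its partners, at 4019 ± 1936 in natural and 3702 ± 1410 in superovulation. Its log2 fold change of -0.09 turned positive when natural replicate 4, natural replicate 5 or superovulation replicate 4 was left out, reaching 0.22. None of the 4 tested gate genes passed limma's test (adjusted p = 0.999 for each).

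No single gene passed the threshold between superovulation and natural libraries. Of the genes named by the rule, IFITM3 had the smallest unadjusted p (0.000512, limma). IFITM3, an interferon-inducible membrane protein that restricts virus entry (chromosome 11, 319676 to 327537), was at 4491 ± 592 in natural (SD, n = 4) and 1936 ± 797 in superovulation (SD, n = 5). Its log2 fold change was -1.30 ± 0.27 (SE), and all 5 superovulation libraries (1088 to 3095) lay below all 4 natural libraries (3943 to 5009). CAST, the calpain inhibitor calpastatin (chromosome 5, from 96525267), was at 748 ± 105 in natural and 1159 ± 230 in superovulation, a log2 fold change of 0.62. Limma called 0 of 15762 genes higher and 0 lower (smallest adjusted p = 0.999), with 307 genes at an unadjusted p under 0.05, of which 165 were higher and 142 lower. That is 1.95% of the genes tested. The groups did not overlap for 0.647% of genes, where chance gives 1.59%.

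The 12 genes named as higher by smallest unadjusted p did not pass limma's test (unadjusted p from 0.00252 to 0.0076, adjusted p = 0.999), and their groups did not overlap for 9 of the 12. KIF16B, a kinesin motor of early endosomes, averaged 55.6 ± 31.8 in natural and 147 ± 30 in superovulation. CCDC150 averaged 72.9 ± 23.2 and 143 ± 31, and IFI27L1, a member of the interferon-inducible IFI27 family, 171 ± 78 and 328 ± 76. The zinc finger gene ZNF432 was at 153 ± 16 and 234 ± 27. PRSS21, the serine protease testisin, was low and variable, at 13.2 ± 6.35 and 72.5 ± 79.2. The mitochondrial gene MT-ND1 was at 9236 ± 2210 and 16023 ± 3723, a log2 fold change of 0.80 that fell to 0.33 once the values of a nuclear copy were added to it. WASH3P and TBC1D3L belong to families of near-identical copies, so their values of 79.2 and 153.0, and of 28.9 and 84.7, are uncertain. AL136295.1, AC040162.1 and AL136419.3 are known only by clone names, with log2 fold changes of 0.95, 0.73 and 0.99.

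The 12 genes named as lower had a smallest unadjusted p of 0.000512 and did not pass limma's test either (adjusted p = 0.999), and 5 of them had groups that did not overlap. Besides IFITM3 they held HIVEP2, a zinc finger transcription factor, at 413 ± 214 in natural and 173 ± 57 in superovulation, and ITGAV, the integrin alpha V chain, at 158 ± 56 and 76.4 ± 25.2. RNASET2, a lysosomal ribonuclease, was at 886 ± 137 and 587 ± 114, and BTN3A2, a butyrophilin with close copies that may share its reads, at 2790 ± 521 and 1953 ± 275. The zinc finger genes ZFP90 and ZNF714 averaged 567 and 231, and 450 and 264. AL512625.3, a long non-coding RNA, averaged 107 and 10.1, and NBPF8, one of a family of near-identical copies, 234 and 85.1. MTND1P23, a nuclear copy of part of MT-ND1 (chromosome 1, 629062 to 629433), ranged from 10.9 to 6656 in natural and from 7.12 to 28.7 in superovulation. It passed limma's test only without natural replicate 5, the library at 10.9 (adjusted p = 0.000105, log2 fold change -8.22).

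**Figure D1:**
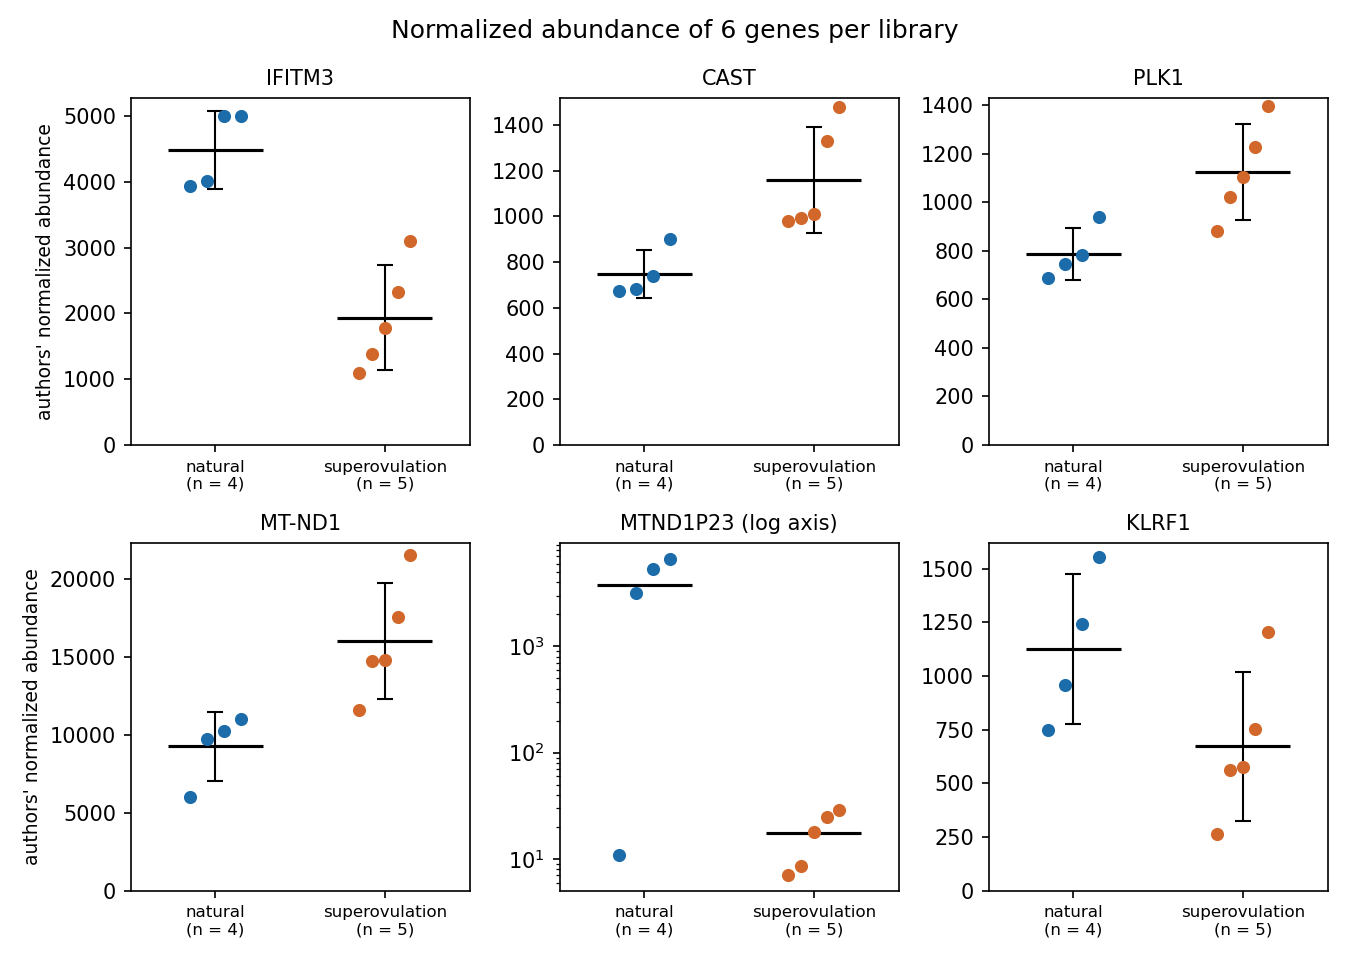
Authors' normalized abundance (vertical axes, linear except for MTND1P23, which has a log axis) of 6 genes in each natural (blue, n = 4) and superovulation (orange, n = 5) library, with the mean as a horizontal line and, on linear axes, the SD as a bar. The 5 superovulation libraries lie below the natural libraries for IFITM3 and above them for CAST, and 1 natural library sits with the superovulation libraries for MTND1P23.

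The authors' deposited table holds 4 genes at an adjusted p under 0.05, and none of them passed limma here. The 2 lower in superovulation are nuclear copies of mitochondrial genes, MTND1P23 and MTCO1P12, with log2 fold changes of -7.77 and -8.34 in the authors' deposited table (adjusted p = 3.28e-07 and 1.13e-05). The 2 higher are KCNK17, a potassium channel subunit (chromosome 6, 39299001 to 39314461), and AC015849.5, a long non-coding RNA (chromosome 17, 35893707 to 35911023), with log2 fold changes of 5.31 and 3.54 in the authors' deposited table (adjusted p = 0.0118 and 0.00566). In limma their log2 fold changes were -6.05, -5.16, 3.89 and 2.83 (adjusted p = 0.999 for each), for MTND1P23, MTCO1P12, KCNK17 and AC015849.5. KCNK17 averaged 0.997 ± 1.42 in natural and 42.5 ± 37.8 in superovulation, and AC015849.5 averaged 1.81 ± 0.44 and 21.8 ± 11.2, and both were named after their values were seen. Signs matched for 92.5% of the 15716 genes with an authors' p, although both come from the same libraries and so are not independent. The authors' shorter list holds 120 higher and 67 lower genes, and 83 of the 187 lay below the filter used here. All 104 that were tested had the same sign in limma, 90 had an unadjusted p under 0.05 and 0 passed the adjusted threshold.

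Cell cycle genes were higher in superovulation as a list. All 32 tested members had a log2 fold change above 0, with a median of 0.32, and camera with a preset correlation gave an adjusted p of 1.7e-14. The call was lost with an estimated correlation of 0.686 between members (adjusted p = 0.585, camera). The mean log2 level of the list was 10.87 ± 0.37 in natural (SD, n = 4) and 11.2 ± 0.27 in superovulation (SD, n = 5). PLK1, a kinase of mitotic entry, averaged 788 ± 108 in natural and 1126 ± 197 in superovulation. CDC20, an activator of the anaphase-promoting complex, averaged 1002 ± 90 and 1365 ± 230, the spindle protein ASPM 1525 ± 324 and 2046 ± 303, and the mitotic kinase AURKB 849 ± 234 and 1204 ± 225. Of the members, 0 passed limma over all genes or adjusted over the list alone. Leaving out natural replicate 4 took the median to 0.18 and leaving out natural replicate 5 took it to 0.50, and the call held in both.

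The 13 mitochondrially encoded genes were also higher as a list, each with a log2 fold change above 0 and a median of 0.30 (camera adjusted p = 2.43e-05 with the preset correlation, 0.585 with an estimated correlation). MT-CO1, a subunit of cytochrome c oxidase, averaged 189520 ± 48488 in natural (SD, n = 4) and 244490 ± 41983 in superovulation (SD, n = 5), and MT-ND4 37092 ± 10967 and 49042 ± 15171. MT-ND4L averaged 5909 and 7490. The mean level of the list per library gave an exact permutation p of 0.254 (Benjamini-Hochberg 0.868). No member passed limma adjusted over the list alone (smallest adjusted p = 0.0553, for MT-ND1). The mitochondrial share of the summed abundance was 6.97 ± 0.94% in natural and 8.94 ± 2.22% in superovulation (two-sided exact permutation p = 0.0794, Benjamini-Hochberg 0.473 over 7 library measures). This share is not that of the 13 genes alone. It includes mitochondrial ribosomal RNA, at 3.44 ± 0.20% in natural and 4.45 ± 1.54% in superovulation (exact permutation p = 0.238). The median was 0.13 without natural replicate 2 and 0.18 without superovulation replicate 4. Nuclear-encoded oxidative phosphorylation genes had 25 of 41 above 0 and were not called in the planned comparison (camera adjusted p = 0.451), with COX8A at 2416 and 2718.

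Interferon response genes were higher as a list, with 25 of 28 tested members above 0 and a median log2 fold change of 0.33 (camera adjusted p = 5.55e-05 with the preset correlation, 0.585 with an estimated correlation). IFI44 averaged 219 ± 114 in natural (SD, n = 4) and 466 ± 274 in superovulation (SD, n = 5), and IFI6 889 ± 227 and 1359 ± 736. The antiviral sensors OAS3 and OAS1 averaged 369 and 615, and 266 and 424. The mean level of the list per library gave an exact permutation p of 0.381 (Benjamini-Hochberg 0.868). No member passed limma over all genes or adjusted over the list alone. The call was lost without natural replicate 5 (camera adjusted p = 0.0685) and without superovulation replicate 4 (camera adjusted p = 0.0592), with medians of 0.24 and 0.15. The median was 0.60 without natural replicate 2 and 0.19 without natural replicate 4.

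NK receptor genes were lower as a list, with 20 of 23 tested members below 0 and a median log2 fold change of -0.26 (camera adjusted p = 0.00852 with the preset correlation, 0.585 with an estimated correlation). KLRF1, which encodes the activating receptor NKp80, averaged 1126 ± 350 in natural (SD, n = 4) and 671 ± 346 in superovulation (SD, n = 5). KLRD1, which encodes CD94, averaged 12049 ± 3918 and 8677 ± 5272, KLRC1 23967 ± 8428 and 17897 ± 8401, and KLRC3 840 ± 289 and 629 ± 225. The mean level of the list per library gave an exact permutation p of 0.333 (Benjamini-Hochberg 0.868). No member passed limma over all genes or adjusted over the list alone. The call was lost without natural replicate 2, superovulation replicate 2 or superovulation replicate 4 (camera adjusted p = 0.22, 0.205 and 0.0592; medians -0.14, -0.16 and -0.18), and without natural replicates 2 and 3 together (camera adjusted p = 0.291, median -0.16). The KIR family, taken as a group, had 6 of 7 tested members below 0 and was not called in the planned comparison (camera adjusted p = 0.489). In the cytotoxic granule list 15 of 18 members were below 0 without a call (camera adjusted p = 0.159), such as CST7, an inhibitor of granule proteases, at 8381 ± 1773 and 6103 ± 3452, and GZMH at 2538 and 1902.

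**Figure D2:**
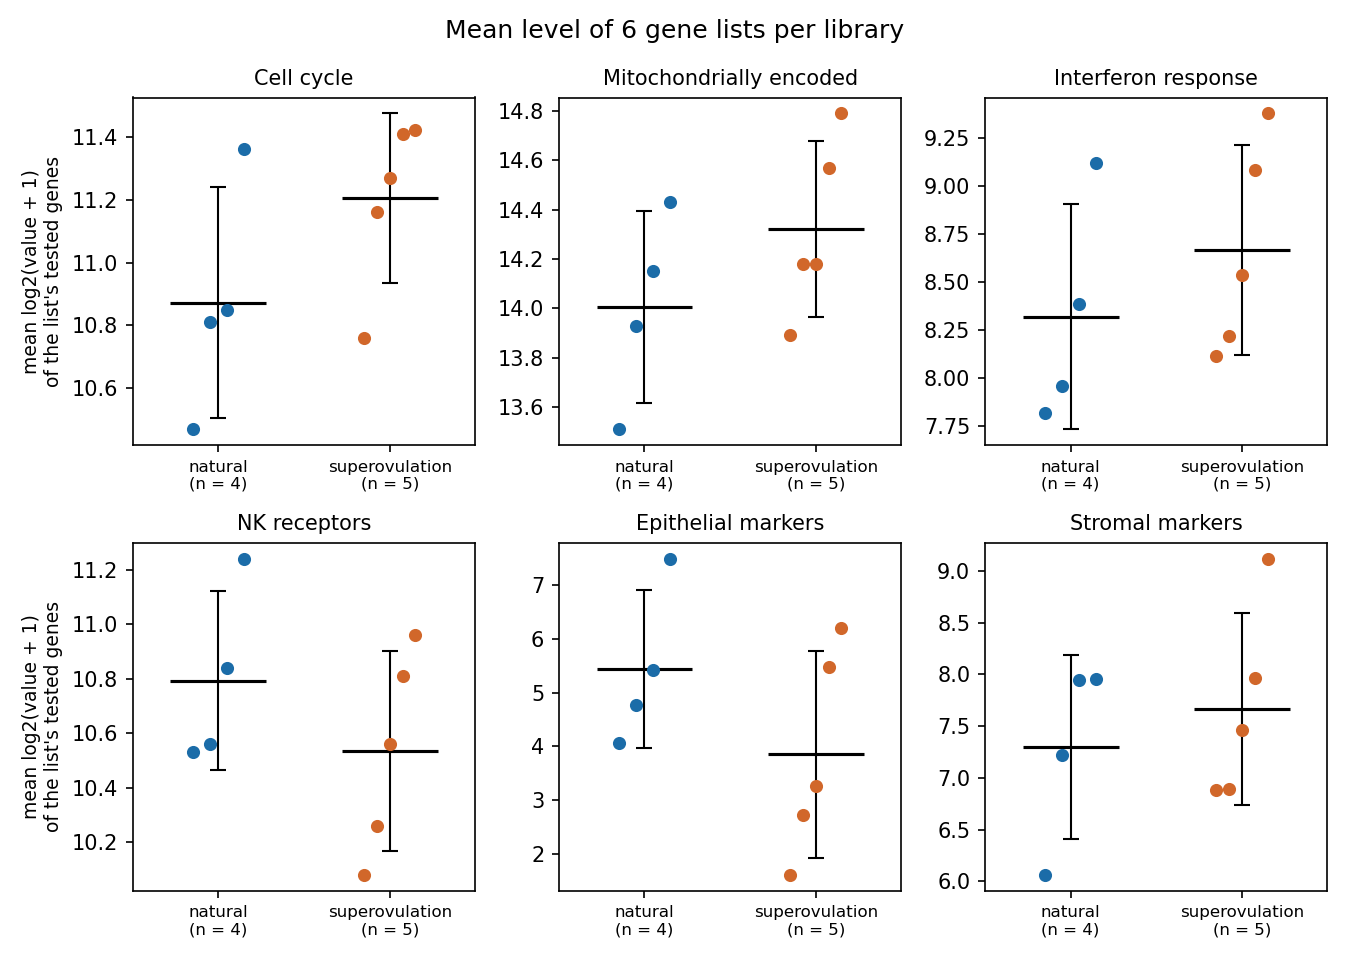
Mean log2(value + 1) of the tested genes of 6 lists (vertical axes, which do not start at 0) in each natural (blue, n = 4) and superovulation (orange, n = 5) library, with the group mean as a horizontal line and the SD as a bar. The groups overlap in all 6 panels, and the cell cycle means are 10.87 and 11.2.

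A further 4 lists passed camera's threshold narrowly and lost it with an estimated correlation. Antigen presentation genes had 19 of 22 members below 0 (median -0.32, camera adjusted p = 0.0325, 0.585 with an estimated correlation). Of their members outside the HLA group, GBP2 averaged 1354 ± 200 in natural (SD, n = 4) and 1087 ± 90 in superovulation (SD, n = 5), and GBP1 706 and 887. Without immunoglobulin, T cell receptor, KIR and HLA genes the list was not called (camera adjusted p = 0.247). IL-15 and STAT5 signalling genes had 17 of 22 below 0 (median -0.12, camera adjusted p = 0.0415, 0.585 with an estimated correlation). For this list the estimated correlation was only 0.000189, and the unadjusted camera p was 0.0121 with the preset and 0.0284 with the estimate. Among its members, STAT5A averaged 723 and 565, SOCS2 758 and 590, JAK1 6307 and 5186, and STAT5B 705 and 613. TGF-beta signalling genes had 16 of 19 below 0 (median -0.23, camera adjusted p = 0.0415, 0.585 with an estimated correlation), such as ITGA1 at 6323 and 4169, SMAD2 at 1536 and 1272, and TGIF1 (log2 fold change -0.71), while LTBP1 averaged 8.57 and 21.0. Ribosomal protein genes had 56 of 75 below 0 (median -0.05, camera adjusted p = 0.0408, 0.803 with an estimated correlation), such as RPL30 at 4533 and 3616, RPS26 at 2053 and 1696, RPS3 at 10235 and 8435, and RPL34 at 3307 and 2799; quantile normalization turned that median to 0.01. No member of these lists passed limma adjusted over the list alone. Their mean levels per library gave exact permutation p-values of 0.46 (antigen presentation), 0.333 (IL-15 and STAT5), 0.603 (TGF-beta) and 0.603 (ribosomal proteins).

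All 4 calls were lost with library totals (camera adjusted p from 0.0524 to 0.0971), with quantile normalization (0.0508 to 0.632) and without natural replicates 2 and 3 (0.166 or more). In the last of these fits the medians of antigen presentation, TGF-beta signalling and ribosomal proteins turned to 0.11, 0.13 and 0.00388. At a CPM of 5 in 4 libraries, antigen presentation (camera adjusted p = 0.0948), IL-15 and STAT5 signalling (0.0948) and ribosomal proteins (0.121) were not called. TGF-beta signalling was not called on the 8 libraries numbered 2 to 5, with the replicate block (camera adjusted p = 0.0578) or without it (0.107). The fit without the block is the same as that without superovulation replicate 1. With the residual covariate, IL-15 and STAT5 signalling was not called (camera adjusted p = 0.0544). Each call was also lost without 1 or another of 5 or 6 single libraries. Antigen presentation was not called without natural replicate 2 (camera adjusted p = 0.22, median -0.11), natural replicate 3 (0.476, median -0.11), or superovulation replicates 2 (0.0809, median -0.39), 4 (0.0803, median -0.29) or 5 (0.158, median -0.13). IL-15 and STAT5 signalling was not called without natural replicates 2 (camera adjusted p = 0.199, median -0.13), 3 (0.134, median -0.19) or 5 (0.0685, median -0.15), or superovulation replicates 2 (0.0888, median -0.13), 4 (0.0917, median -0.06) or 5 (0.158, median -0.145). TGF-beta signalling was not called without natural replicates 2 (camera adjusted p = 0.868, median -0.01) or 3 (0.148, median -0.185), or superovulation replicates 1 (0.107, median -0.13), 2 (0.098, median -0.21), 4 (0.104, median -0.20) or 5 (0.164, median -0.185). Ribosomal proteins were not called without natural replicates 2 (camera adjusted p = 0.29, median -0.0337), 3 (0.219, median -0.0399) or 5 (0.589, median -0.00286), or superovulation replicates 3 (0.859, median -0.00648) or 5 (0.581, median -0.00444).

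Lists that describe uterine NK cell states were not called by camera in the planned comparison, and some passed under other settings. Tissue-resident uterine NK genes had 14 of 22 members below 0 (camera adjusted p = 0.195), with KRT81 at 2523 ± 463 in natural (SD, n = 4) and 1777 ± 592 in superovulation (SD, n = 5). Genes of uterine NK subset 1 had 7 of 10 above 0 (camera adjusted p = 0.203), such as SPINK2 at 2356 and 3537 and ZNF90 at 50.1 and 69.0, and those of subsets 2 and 3 had 8 of 12 below 0 (camera adjusted p = 0.867), such as XCL2 at 16475 and 14713. ITGB2, the integrin beta 2 chain, averaged 3453 ± 952 and 5853 ± 1948. It had the smallest unadjusted p of the subset 2 and 3 list (0.0223, limma) and went against the direction of most of its members. Blood NK genes had 10 of 14 above 0 (camera adjusted p = 0.458), with CD52 at 7607 and 10608 and the Fc receptor FCGR3A at 161 and 105. NK transcription factors had 19 of 27 below 0 (camera adjusted p = 0.219), with LEF1 at 1050 and 756 and MAF at 32.0 and 49.3.

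Lists of hormone action, secretion and stress were not called there either, and some passed under other settings. Steroid receptor targets had 16 of 23 members below 0 (camera adjusted p = 0.159), with the metallothionein MT1E at 128 ± 102 in natural (SD, n = 4) and 31.6 ± 30.2 in superovulation (SD, n = 5) and TXNIP at 7241 ± 3098 and 4312 ± 1666. Hormone receptors had 6 of 9 below 0 (camera adjusted p = 0.32), with the glucocorticoid receptor NR3C1 at 1865 and 1407 and PGRMC2 at 428 and 346. Secreted factors had 12 of 21 above 0 (camera adjusted p = 0.613), with IL32 at 7641 and 5805 and TNF at 726 and 1167. Angiogenic factors had 11 of 16 above 0 (camera adjusted p = 0.0838), with TIMP1 at 322 and 499. Migration and adhesion genes had 17 of 25 below 0 (camera adjusted p = 0.169; CXCR3 at 2367 and 1800), and checkpoint receptors 11 of 15 (camera adjusted p = 0.387; TNFRSF9 at 206 and 117, ICOS at 134 and 106). Immediate early genes, which tissue dissociation can induce, had 19 of 31 above 0 (camera adjusted p = 0.139), with ATF3 at 141 and 285 and EGR3 at 85.3 and 152. The unfolded protein response had 13 of 21 below 0 (camera adjusted p = 0.469; EIF2AK3 at 444 and 324, MANF at 793 and 980), glycolysis and hypoxia 17 of 29 (camera adjusted p = 0.489; P4HA1 at 583 and 443, BNIP3L at 978 and 691), and apoptosis and p53 genes 12 of 22 (camera adjusted p = 0.772; TNFRSF10B at 190 and 250, CDKN1A at 1097 and 1364). For apoptosis and p53 genes the median was -0.02 while the mean and camera pointed up.

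Markers of cells outside the gate varied between libraries in both groups. Epithelial markers had the widest gap, with a mean log2(CPM + 1) of 2.0 ± 1.08 in natural (SD, n = 4) and 1.13 ± 0.77 in superovulation (SD, n = 5; two-sided exact permutation p = 0.206, Benjamini-Hochberg 0.715 over 9 lists). Their summed CPM averaged 222 and 70.5 and ranged from 13.0 to 525 between libraries. KRT19 averaged 141 ± 130 and 18.3 ± 20.6, KRT8 114 ± 118 and 11.7 ± 8.78, SCGB2A1 595 ± 942 and 34.8 ± 54.4, and DEFB1 160 ± 251 and 24.9 ± 34.2. In camera, 16 of 17 tested epithelial members were below 0 (median -1.52, adjusted p = 3.14e-05 with the preset correlation, 0.585 with an estimated correlation), and the call was lost without natural replicate 3 (adjusted p = 0.0985, median -0.86) and without natural replicates 2 and 3 together (adjusted p = 0.383, median -0.74). Natural replicates 2 and 3 were picked for having the most epithelial RNA of the natural libraries, so a smaller epithelial gap without them follows from that choice. The median was -1.01 without superovulation replicate 4 and also -1.01 without superovulation replicate 5. Stromal markers had 19 of 22 above 0 (median 0.29, camera adjusted p = 0.0409 with the preset correlation, 0.642 with an estimated correlation), with COL6A2 at 118 and 257, COL6A3 at 89.3 and 156, IGFBP5 at 51.9 and 130, and HOXA10 at 436 and 299. Superovulation replicate 2 raised the first 3 of these means, with COL6A2 at 758, COL6A3 at 403 and IGFBP5 at 401. The call was lost without natural replicates 2 (camera adjusted p = 0.174, median 0.25) or 4 (0.911, median 0.04), or superovulation replicates 2 (0.924, median 0.02) or 3 (0.0875, median 0.33), with no low filter (0.238), with library totals (0.0596) and with quantile normalization (0.0641). The stromal mean log2(CPM + 1) was 3.55 ± 0.61 and 3.81 ± 0.77 (exact permutation p = 0.619).

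The remaining marker lists were not called in the planned comparison. T cell markers averaged 4.01 and 3.84 on the log2(CPM + 1) scale in natural and superovulation (exact permutation p = 0.365; camera adjusted p = 0.195), with 10 of 12 tested members below 0 and a median log2 fold change of -0.21. CD6, 1 of the 2 above 0, averaged 148 and 225, with superovulation replicate 3 at 580. Markers of group 2 and 3 innate lymphoid cells averaged 2.18 and 2.40 (exact permutation p = 0.857, camera adjusted p = 0.489). KIT averaged 108 ± 46 and 388 ± 548, with superovulation replicate 3 at 1356.5, and TNFSF11 averaged 164 and 93.8. B and plasma cell markers averaged 1.60 and 1.67 (exact permutation p = 0.333; camera adjusted p = 0.264; PAX5 at 11.6 and 17.1), and endothelial and muscle markers 1.55 and 1.68 (exact permutation p = 0.778; camera adjusted p = 0.262; TAGLN at 34.6 and 66.0, MYH11 at 41.7 and 60.8). Myeloid markers averaged 0.70 and 0.61 (exact permutation p = 0.397, with LYZ at 493 and 226), and neutrophil and mast cell markers 0.39 and 0.55 (exact permutation p = 0.27). Red cell and platelet markers averaged 0.40 and 0.42 (exact permutation p = 0.984). These 3 lists had too few tested members for camera. HBB and HBA2 had log2 fold changes of 0.99 and 0.06, although their means fell from 185 to 66.7 and from 66.5 to 24.4. Their lowest natural values were 1.37 and 0.

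The libraries did not separate by group. The first component of the 500 most variable genes held 29.7% of the variance (exact permutation p = 0.619 between groups) and set natural replicate 4 and superovulation replicates 4 and 5, with scores from 26.0 to 39.4, apart from the other libraries, with scores from -27.4 to -1.99. The second held 16.5% (exact permutation p = 0.159). Across genes, libraries of the same group correlated at a mean of 0.925 and libraries of different groups at a mean of 0.93.

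**Figure D3:**
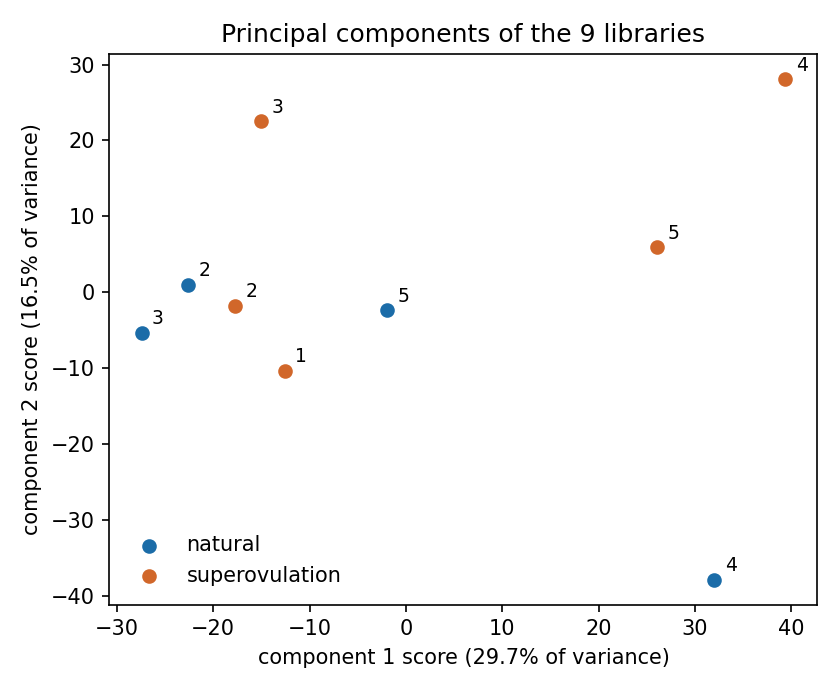
Scores of the 9 libraries on the first (horizontal, 29.7% of variance) and second (vertical, 16.5% of variance) principal components of log2(value + 1) of the 500 most variable genes, without units, with natural in blue, superovulation in orange and replicate numbers beside the points. Both groups spread over the first component, and neither forms a cluster of its own.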

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

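All tests of explanations in this part were chosen after the results were seen, except the counts of other splits of the samples for genes and for lists past the threshold.

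In 286 groups of 4 or 5 libraries, 13 had a highest or lowest library set apart from the others by Dixon's criterion, where chance gives about 1 in 20 (14.3), so these flags are about as many as chance would give. The mitochondrial share was 12.8% in superovulation replicate 4 against 6.99% to 8.62% in the other superovulation libraries. The mean log2 level of tissue-resident genes was 11.7 in natural replicate 4 (others 11.3 to 11.4), and that of blood NK genes was 8.37 in superovulation replicate 3 (others 7.82 to 7.94). In natural replicate 3, AL136295.1 was at 93.3 (others 139 to 146). In natural replicate 4, ITGAV was at 242 (others at most 136) and IGFBP5 at 4.16 (others 58.1 to 85.9). In natural replicate 5, MTND1P23 was at 10.9 (others 3180 to 6660) and STAT5A at 510 (others 772 to 815). In superovulation replicate 4, ITGA1 was at 2560 (others 4170 to 4940) and IFI6 at 2650 (others 891 to 1200). In superovulation replicate 5, IL32 was at 2160 (others 6280 to 7600), CDC20 at 963 (others 1420 to 1550) and AURKB at 812 (others 1260 to 1380).

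The nuclear copies MTND1P23 and MTCO1P12, the 2 lower genes past the threshold of the authors' deposited comparison, were each above all superovulation libraries in 3 of the 4 natural libraries, reaching 6656 and 49390 where superovulation reached 28.7 and 69.8. Genomic DNA in the natural libraries is argued against, because the other 3 tested copies in the same block of chromosome 1 (MTND2P28, MTATP6P1 and MTCO3P12) had a median log2 fold change of 1.2, not below -1, and it stayed above -1 (lowest -0.325) when any 1 library was left out. The high values of MTND2P28 and MTCO3P12 (3773 and 2652) were both in superovulation replicate 1 alone, and in natural libraries these copies reached no more than 102.1 and 19.05. Reads shared with the mitochondrial genes are a candidate explanation that these values cannot decide. Adding MTND1P23 to MT-ND1 took the excess of MT-ND1 over the median of the other mitochondrial genes from 0.522 to 0.0472. Adding MTCO1P12 to MT-CO1 took that of MT-CO1 from 0.112 to -0.0244. A fall was fixed in advance, because both copies were lower in superovulation. The excess of MT-CO1 was also smaller than the SE of its log2 fold change (0.219), so little was there to remove. An effect of the treatment cannot be told apart from a difference between donors in how well their mitochondrial sequence matches the reference, because only 3 of the 4 natural libraries show the pattern and donor sequence was not examined.

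Cell cycle genes were higher in superovulation with the preset correlation. The authors' scaling of the libraries is argued against as the source, since the median log2 fold change of the list was 0.323 at the least under 3 other scalings. Of these, median-of-ratios scaling left the authors' values almost unchanged (0.323), while library totals gave 0.342 and quantile normalization 0.372. Chance in how the libraries are grouped stays open, as 7 of 100 splits of the 9 libraries into 4 and 5, the real one included, gave a camera p as small (-log10 of p 15.3 in the real split and 28.1 in the highest other). Genes that move together across libraries stay open as well, since the estimated correlation was 0.686 and the unadjusted camera p with it was 0.0896. A larger share of dividing NK cells after superovulation is the biological explanation the design offers, and it may hold but was not tested.

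Limma's count of 0 genes past the threshold says nothing about chance, since any split reaches it (100 of 100 splits, with 49 genes in the highest other). The 307 genes at an unadjusted p under 0.05 were reached by 91 of 100 splits, with 2650 genes in the highest other, so chance is not excluded. That split, the highest of those drawn, sets natural replicates 2 and 3 with superovulation replicates 3 and 4. Its count was several times the real one, and whether a structure of the samples other than the groups lies behind it was not tested. The 10 lists past the threshold of camera with the preset correlation were reached by 36 of 100 splits, with 18 lists in the highest other, so chance is not excluded for these either.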

How the results depend on the processing

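The covariate from the residuals, library totals, quantile normalization and the fit without natural replicates 2 and 3 were chosen after seeing the data. Under every alternative run, limma called 0 genes higher, and it called 0 lower except without natural replicate 5 (1 gene, MTND1P23), so leaving out single libraries gave 0 to 1 lower genes. The planned Wald test was not run because it needs counts, and the planned surrogate variable from sva was not run, with the residual component in its place. That component is independent of group by construction, so it leaves fold changes as they are. The cell cycle and mitochondrially encoded lists were called under all 12 other settings of the preset test and without each of the 9 libraries. The fit with no block on the 8 libraries numbered 2 to 5 is also that without superovulation replicate 1, so these counts hold it in both. Camera gave 4 higher and 6 lower lists. With an estimated correlation it gave 0 and 0 (0 and 1 at an unadjusted p under 0.05), and fry gave 0 and 0 (0 and 0 unadjusted, smallest adjusted p = 0.828). Lower lists numbered 13 with no low filter, 2 at a CPM of 5 in 4 libraries, 2 with library totals, 2 with quantile normalization, and 1 to 7 with single libraries left out. They numbered 3 without natural replicate 2, 1 without natural replicate 3, 2 without superovulation replicate 2, and 3 without superovulation replicate 4 or 5. Higher lists numbered 9 without natural replicates 2 and 3. The cause of these shifts was not tested. Signs matched the authors' table for 75.2% to 94.2% of genes over all settings.

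Same-numbered libraries deviated from their group means with correlations of -0.137, 0.236, 0.107 and 0.0433 for numbers 2 to 5. Of the natural libraries, only replicate 3 correlated best with its own number. Natural replicates 2, 4 and 5 correlated best with superovulation replicates 3 (0.365), 5 (0.278) and 2 (0.253). The numbers were therefore not taken as pairs. With the replicate block, limma called 0 and 0 genes and camera called 6 higher and 6 lower lists, against 5 and 5 with no replicate block on the same 8 libraries.

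Without natural replicates 2 and 3, 3 called lists changed sign and lost their calls, namely TGF-beta signalling (median log2 fold change 0.133, camera adjusted p = 0.378), antigen presentation (0.106, adjusted p = 0.166) and ribosomal proteins (0.00388). NK receptors (-0.156, camera adjusted p = 0.291) and IL-15 and STAT5 signalling (-0.165, adjusted p = 0.522) lost theirs too. So did epithelial markers (-0.741, camera adjusted p = 0.383), where a smaller gap follows from picking these libraries for their epithelial RNA. That fit took libraries out of the natural group only, while superovulation replicates 1 and 2, also high in epithelial markers, stayed in. Its sign changes therefore do not show the comparison without epithelial RNA. Uterine NK subset 1 (-0.236, camera adjusted p = 0.0482), subsets 2 and 3 (0.464, adjusted p = 0.00326) and oxidative phosphorylation (-0.109, adjusted p = 0.0358) passed in the direction opposite to that of all libraries. Lists that gained a call there, in the direction of all libraries, were the KIR family (-0.989, camera adjusted p = 0.00113), cytotoxic granules (-0.352, adjusted p = 0.00418), tissue-resident genes (-0.147, adjusted p = 0.0418), secreted factors (0.431, adjusted p = 0.00929), angiogenic factors (0.633, adjusted p = 0.0196), immediate early genes (0.222, adjusted p = 0.00326) and innate lymphoid markers (1.14, adjusted p = 0.0358). Uncalled there and changed in sign were steroid targets 0.285 and checkpoint receptors 0.095, and the log2 fold changes were SPINK2 -0.181, FCGR3A 0.312, TNFRSF9 0.414, ICOS 0.191 and CDKN1A -0.0806. Over all 21 other settings of the preset test, 9 of them with 1 library left out, lists not called in the planned comparison passed in 8 (immediate early genes), 5 (each of cytotoxic granules, angiogenic factors and steroid targets), 4 (oxidative phosphorylation) or fewer. Of these settings, that with no block on 8 libraries and that without superovulation replicate 1 are the same fit, and the count for immediate early genes holds both. Quantile normalization gave ribosomal proteins 0.00641, glycolysis and hypoxia 0.0342, apoptosis and p53 0.0155, secreted factors -0.00157 and HBA2 -0.158. Library totals gave glycolysis and hypoxia 0.00123 and apoptosis and p53 0.00232. Quality weights gave CD3E 0.158, HBA2 -0.475 and secreted factors -0.00168. With no low filter, blood NK was at -0.0321. On the 8 libraries numbered 2 to 5, oxidative phosphorylation was at -0.045 and HBA2 at -0.26, with and without the block.

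With single libraries left out, ranges that crossed 0 were CD3E -0.437 to 0.22, HBB -0.152 to 2.56, HBA2 -1.32 to 1.29, the KIR family -0.687 to 0.13, uterine NK subset 1 -0.0744 to 0.524, subsets 2 and 3 -0.3 to 0.182, blood NK -0.0759 to 0.244, secreted factors -0.157 to 0.24, steroid targets -0.278 to 0.113, immediate early genes -0.112 to 0.253, glycolysis and hypoxia -0.08 to 0.0403, oxidative phosphorylation -0.045 to 0.123, apoptosis and p53 -0.068 to 0.0599, innate lymphoid markers -0.435 to 0.704 and endothelial and muscle markers -0.00831 to 0.634. In the permutation test of log2(CPM + 1), such ranges were innate lymphoid -0.269 to 0.493, myeloid -0.202 to 0.0356, stromal -0.0469 to 0.425, endothelial and muscle -0.0398 to 0.224, and red cell and platelet markers -0.0758 to 0.17.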

Other observations

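All tests in this part were chosen after the results were seen. The interferon-inducible membrane protein genes IFITM1 and IFITM2, which belong to no list and were named after their values were seen, lay with IFITM3 on chromosome 11 between 307631 and 327537 and had the same direction. IFITM1 was at 32780 ± 11960 in natural (SD, n = 4) and 15920 ± 7277 in superovulation (SD, n = 5), and IFITM2 at 20330 ± 3895 and 10770 ± 4420. For each of the 3 genes all 5 superovulation libraries lay below the lowest natural library, and none passed limma's test (adjusted p = 0.999, log2 fold changes -1.19, -1.05 and -1.30 for IFITM1, IFITM2 and IFITM3). The log2 fold change of their sum was -1.13 ± 0.455 (SE; two-sided exact permutation p = 0.0159, the smallest 4 against 5 libraries can give), for genes picked because they differed. Of 100 splits of the libraries, the real one included, 1 gave a mean fold change of the 3 genes as large. This says nothing further about chance, because genes picked with no overlap between the groups leave few splits that could reach it. In the deposited coordinates IFITM1 (313506 to 315272) lies within IFITM2 (307631 to 315272), so the 3 genes may not be separate observations.

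The lower IFITM level is not explained by reads that moved among these 3 genes, since their sum was lower too (-1.13). Reads counted for other genes or dropped as ambiguous are not covered by this sum. The interferon response list, which holds none of the 3 genes, pointed the other way, with a median log2 fold change of 0.326 and 25 of 28 members above 0. A lower interferon response still stays open, because the mean of that list differed by less than its standard error (0.348 ± 0.38; exact permutation p = 0.381). A single library is argued against, as the log2 fold change of the sum stayed between -1.26 and -0.769 with each of the 9 libraries left out. An effect of superovulation on these genes, a difference in NK cell maturity and chance among 15762 genes may each account for the pattern and stay open.

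Superovulation replicate 3 held the highest mean of group 2 and 3 innate lymphoid markers, 8.65 on the log2 scale against 4.30 to 6.93 in the other 8 libraries, with KIT at 1356 and IL4I1 at 505. Epithelial markers were highest in natural replicate 3, at a mean log2 level of 7.50, and lowest in superovulation replicate 4, at 1.61. Without superovulation replicate 3 the median log2 fold change of the innate lymphoid list was -0.44.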
